A study of Mus musculus with 4 samples.

How the data were processed

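CD4 T cells were sorted from mouse spleens 14 days after an allogeneic transplant, and their RNA was sequenced as bulk libraries. Donors were B10.D2 mice and recipients were BALB/c mice irradiated with 850 cGy, which received splenocytes and bone marrow cells. Effector memory cells (Tem) were gated as CD4+CD1d−CCR7−CD44high, and naive cells (Tn) as CD4+CD1d−CCR7+CD44low, with a stated sort purity of 95%. The gates as stated hold no marker of donor origin, so donor and recipient cells are not told apart below. Ribosomal RNA was depleted from total RNA before library preparation. Each of the 4 libraries (3 Tem and 1 Tn) holds RNA of a pool of cells from several mice. Whether the 3 Tem pools came from separate mice is not given in the sources used here, so p-values measure only the spread between pools.

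The main table deposited by the authors holds normalised signal: counts scaled to library size and by TMM (trimmed mean of M values), a library factor computed by the authors. In each library all values (100%) were whole multiples of the value of 1 read, within 0.01 of a whole read, so the reads behind each value were recovered. Columns of this deposited signal summed to between 972624 and 1049921, and values are called CPM below. The test had been planned for CPM and was left unchanged. The authors also deposited FPKM values for the 4 libraries and TPM values for the Tem libraries. TPM values of the Tn library were derived here from the deposited FPKM, a step that gave the deposited TPM of the Tem libraries within 0.0959. The authors' results table holds log2 fold changes and mean log2 expression, a p-value and an adjusted p-value per gene, and scores (the moderated statistic, the log-odds and a signed fold). Other deposited columns are lists of genes chosen by the authors for T helper types, apoptosis and metabolism, with a pathway name for each metabolic gene.

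The submitters' processing notes name Trimmomatic 0.33, STAR 2.5.2b, RSEM 1.3.0 and limma 3.34.5. They name the builds GRCh37, hg19 and mm10 with no role for each. The 49585 gene identifiers are mouse Ensembl identifiers, and 49326 of them (99.5%) are in GENCODE M21. Coordinates below are those of GENCODE M21 on GRCm38, taken by identifier. The annotation release used by the authors is not given in the sources used here.

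Recovered reads came to 32946265, 46655386 and 46218833 in Tem replicates 1, 2 and 3, and to 45537721 in the Tn library. At these depths 1 read was worth 0.0295, 0.0215, 0.0218 and 0.0231 CPM, and a gene with no read could still have stood at 0.0886, 0.0645, 0.0654 and 0.0692 CPM (3 reads). Reads carry no molecular identifiers, so these floors cover counting error only. Differences between Tem libraries were beyond read sampling, with chi-square per degree of freedom of 90.3, 114 and 17.2 for the 3 pairs, so none is a copy of another.

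The tests, gene lists and naming rule in this and the next 2 paragraphs were fixed before the data were examined. The minimum of 3 genes per list and the matching of symbols were set afterwards. Genes with at least 1 CPM in at least 1 library were tested, 14125 in all. Values were taken as log2(CPM + 0.5), and Tem was compared with Tn by limma 3.58.1 with an intensity trend on the variance. The pseudocount shrinks the log2 fold change of a gene whose level in a group is near or below 0.5 CPM. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called changed, two-sided. The residual variance has 2 degrees of freedom, all from the Tem libraries, and limma's prior adds 3.31. The lone Tn library is assumed to vary like the Tem libraries. Adjusted p-values of single genes below are from this limma model.

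Gene lists numbered 39, for metabolism, T cell states, cell cycle, stress, and markers of other cell types in spleen. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists that had at least 3 genes tested. Camera with an estimated correlation and fry were run as other tests. With 2 residual degrees of freedom that correlation is poorly estimated, and the test that uses it called 0 of 37 lists. A list that does not pass it is therefore not shown to be unchanged. Calls at the preset correlation still rest on that preset. The adjusted p of a list is camera's with the preset correlation unless another is named. Lists said to be higher or lower are called by that test. Those that fry did and did not call are named in the section on how the results depend on the processing. Members past the threshold were counted over all genes tested, and again adjusted over the list alone. The 21 lists of the study with at least 3 genes tested were run apart, with symbols matched without regard to capitals.

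Genes named in the text follow a rule. It takes the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 10 CPM, and all 3 Tem libraries on one side of the Tn library. Predicted genes, Rik genes and antigen receptor segments were passed over. From each list it takes up to 4 members past the threshold with the largest change, and up to 2 others with the highest mean. Finally it takes a set of sorting, glycolysis and T cell genes whatever their values. Some genes taken by this rule are not reported here. A gene named outside this rule is said to be chosen after its values were seen.

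Other settings fixed at that stage were pseudocounts of 0.1 and 2, no filter, a filter on a mean of at least 5 CPM, TPM, FPKM, median-of-ratios scaling, quantile normalization, no variance trend, a robust prior, each Tem library left out in turn, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and Tem replicate 3 alone against Tn. Chosen after seeing the data were edgeR with the deposited scaling, structural RNA genes left out (also with TPM), and removal of a trend on gene length. Families of related genes in the closing section were also chosen after seeing the data, by symbol or, for cytokine receptors, by hand, with 1 entry per symbol and without binding proteins, opposite-strand transcripts and unrelated genes of like symbols.

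The models were tested on simulated data with the same group sizes and depths, 5 runs with 200 changed genes each. Limma recovered 45.6% of 2-fold and 70.8% of 4-fold changes, and 13.1% of its calls were false. For edgeR these shares were 48.6%, 71.2% and 14.3%, and for DESeq2 56.0%, 78.2% and 28.8%. Camera called 2 of 200 unchanged simulated lists and 50 of 50 raised ones, and fry called 1 and 28. Simulated genes were drawn independently, so members of a simulated list were not correlated. In the real lists the estimated correlation ran from 0.0667 (glucose and lactate transport) to 0.971 (neutrophil). The simulated Tn library was drawn with the dispersions of the Tem libraries. The simulation therefore does not test the preset correlation, nor the assumption that Tn varies like Tem. It also changed far fewer genes than the 3072 called in the data, with rises and falls in equal number. Its shares of recovered changes and of false calls therefore do not carry over to the real calls. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A second copy of the study's gene lists was left out because it held the same content.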

Results

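RNA was measured in 4 libraries of CD4 T cells sorted from the spleen of mice 14 days after an allogeneic transplant: 3 pools of effector memory cells (Tem) and 1 pool of naive cells (Tn). Libraries held 32946265 to 46655386 reads, and between 22119 and 22473 genes had at least 1 read. Structural RNA genes (ribosomal, 7SK, 7SL, RNase P and RNase MRP) took 16.9%, 14.2% and 13.5% of reads in Tem replicates 1 to 3 and 23.9% in Tn. Mitochondrial genes took 1.22%, 0.680%, 0.722% and 0.781%, and protein-coding genes 78.9%, 83.0%, 83.8% and 72.7%, in the same order. On the first principal component, which held 69.6% of the variance, Tn stood at 71.7 and the Tem libraries between −26.2 and −20.2. On the second, with 26.4%, Tem replicate 1 stood at 42.4 and the other Tem libraries at −18.8 and −21.1. Values below are Tem means ± SD (n = 3) in CPM against the single Tn value, which has no replicate, and log2 fold changes of Tem over Tn ± SE.

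The comparison of Tem with Tn asked how the transcriptome of effector memory CD4 T cells, glycolysis in particular, differs from that of naive cells. Both were sorted 14 days after transplant, and whether they came from the same mice is not given in the sources used here. The effector memory list was higher in Tem (19 rises of 20 genes) and the naive list was lower (14 falls and 1 rise of 18) by camera at the preset correlation, though not at an estimated one (adjusted p = 0.746 for both). Cxcr6, a chemokine receptor of tissue-homing T cells, stood at 235 ± 25.7 CPM in Tem and 13.7 in Tn, a log2 fold change of 4.04 ± 0.15 (adjusted p = 0.00169). Igfbp4, a binding protein of insulin-like growth factors, stood at 0.399 ± 0.116 CPM in Tem and 623 in Tn, and fell by 9.45 ± 0.25 on the log2 scale (adjusted p = 0.0016). Hk2, the inducible hexokinase of the first step of glycolysis, rose by 1.48 ± 0.15, from 8.39 CPM in Tn to 24.4 ± 1.67 in Tem (adjusted p = 0.00478). Ldha, the lactate dehydrogenase subunit that favours lactate formation, stood at 560 ± 65.0 CPM in Tem and 471 in Tn and did not pass (0.24 ± 0.18, adjusted p = 0.382).

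Of 14125 genes tested, 1868 rose in Tem and 1204 fell (limma, adjusted p under 0.05), and 995 and 713 of these changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 5322 genes. All 3 Tem libraries lay on one side of Tn for 10639 genes (75.3%). Among so few libraries, a lone library is often the highest or the lowest by chance alone. This share is therefore no measure of how many genes differ between Tem and Tn. Rises made up 60.8% of the changed genes, against 16.1% with TPM, 44.6% with TPM without structural RNA genes, 50.7% after quantile normalization and 46.3% with edgeR and its own TMM factors. The median log2 fold change of all genes tested was 0.07, against −0.32 with TPM, −0.06 with TPM without structural RNA genes and −0.04 with edgeR, so the balance of rises and falls depends on the scaling. Without Tem replicate 1 the changed genes numbered 7673, and without Tem replicate 2 they numbered 1456, against 3072 with all libraries.

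**Figure D1:**
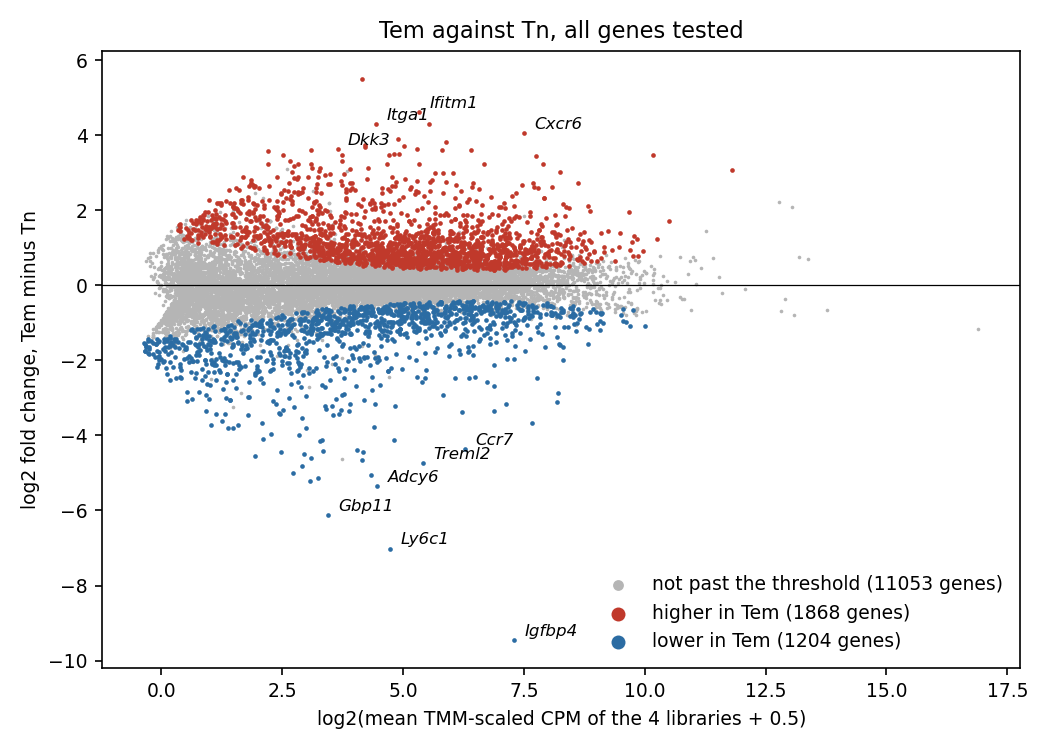
Mean expression over the 4 libraries (CPM, log axis) against the log2 fold change of Tem over Tn for 14125 genes, with genes past an adjusted p of 0.05 in colour and some of the genes of largest change named. Of the coloured genes, 1868 lie above 0 and 1204 below.

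By the naming rule the largest rise was in Ifitm1 (ENSMUSG00000025491, GRCm38 chromosome 7, 140967221 to 140969825, plus strand), an interferon-induced membrane protein, which rose by 4.62 ± 0.35, from 1.57 to 52.2 ± 15.6 CPM (adjusted p = 0.00249). Itga1 (ENSMUSG00000042284, chromosome 13, 114953096 to 115101964, minus strand), the collagen-binding integrin alpha subunit of tissue-resident T cells, rose by 4.30 ± 0.24, from 0.922 to 27.8 ± 4.92 CPM (adjusted p = 0.00169). Cxcr6 (ENSMUSG00000048521) lies on chromosome 9, 123806475 to 123811760, plus strand. Klrc1 and Klrk1, which encode the lectin-like receptors NKG2A and NKG2D, rose by 4.28 ± 0.20 and 3.88 ± 0.18. Sostdc1, Ifitm2, Cd109 and Dkk3 were among the others, with log2 fold changes of 3.81, 3.70, 3.68 and 3.62.

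The largest falls included Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392, plus strand) and Ly6c1 (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830, minus strand), a Ly6 surface antigen, which fell by 7.02 ± 0.28, from 103 CPM to 0.30 ± 0.105. Gbp11, annotated as a polymorphic pseudogene of the guanylate-binding proteins, held 3 to 5 reads per Tem library and 1785 in Tn, a ratio of 433 with a 95% exact binomial counting interval of 247 to 840. Adcy6, an adenylate cyclase, and Treml2 fell by 5.34 ± 0.20 and 4.75 ± 0.23. Irs2, an insulin receptor substrate, and Oas2, an interferon-induced oligoadenylate synthetase, fell by 4.66 ± 0.28 and 4.45 ± 0.27. Myo6, Ccr7 and Vipr1, the first receptor of vasoactive intestinal peptide, fell by 4.40, 4.36 and 4.13. Ccr7 and Cd44 define the gates and are no findings here: Ccr7 stood at 12.8 ± 1.16 CPM in Tem and 271 in Tn, and Cd44 at 340 ± 41.7 and 55.0. The other gate genes, Cd4 and Cd1d1, had log2 fold changes of 0.67 (adjusted p = 0.0784) and −0.72 (adjusted p = 0.0231).

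The glycolysis list as a whole did not pass. Of 19 genes tested, 5 rose, 2 fell and 12 did not pass over all genes; adjusted over the list alone, 7 rose and 2 fell. The list had a median log2 fold change of 0.38 (mean 0.17, adjusted p = 0.139), and of 0.07 with TPM, where the median over all genes was −0.32. Tpi1, the triosephosphate isomerase, rose by 0.97 ± 0.11, from 78.2 to 154 ± 5.0 CPM (adjusted p = 0.00665). Pgk1, the phosphoglycerate kinase of the first ATP-forming step, rose by 0.80 ± 0.13, from 164 to 286 ± 14.2 CPM (adjusted p = 0.0139). Pfkp, a phosphofructokinase subunit, rose by 0.54 ± 0.12 (adjusted p = 0.0373), and Pgam1, named after its values were seen, by 0.63 ± 0.13 (adjusted p = 0.0258). Eno3, the muscle enolase, and Ldhb, the subunit that favours lactate use, were low in both groups and fell by 1.81 ± 0.19 and 1.50 ± 0.22 (adjusted p = 0.00515 and 0.0122).

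Gapdh, Pkm, Eno1, Hk1 and Pfkl lay above Tn without passing. Gapdh stood at 1425 ± 219 CPM in Tem and 821 in Tn (0.78 ± 0.25, adjusted p = 0.0794), and Pkm, the pyruvate kinase of T cells, at 881 ± 80.2 and 634 (0.47 ± 0.18, adjusted p = 0.129). For Eno1, Hk1 and Pfkl the log2 fold changes were 0.48, 0.38 and 0.23 (adjusted p = 0.118, 0.140 and 0.200). In the authors' own results for this contrast, Gapdh, Pkm and Eno1 were higher at an adjusted p under 0.05 (log2 fold changes of 0.81, 0.49 and 0.50). Hk1, Pfkl and Ldha were not past that threshold there. Whether further libraries entered those results is not given in the sources used here. Hk2 (ENSMUSG00000000628) lies on GRCm38 chromosome 6, 82725025 to 82774454, minus strand, and Ldha (ENSMUSG00000063229) on chromosome 7, 46841475 to 46855627, plus strand. The list passed without Tem replicate 1 (median 0.46, adjusted p = 0.0470), the library that stands apart on the second principal component, against adjusted p = 0.346 and 0.366 without Tem replicate 2 or 3. Without Tem replicate 2, Pgk1 and Pfkp no longer passed (adjusted p = 0.0725 and 0.142), nor did Pfkp without Tem replicate 3 (adjusted p = 0.134).

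**Figure D2:**
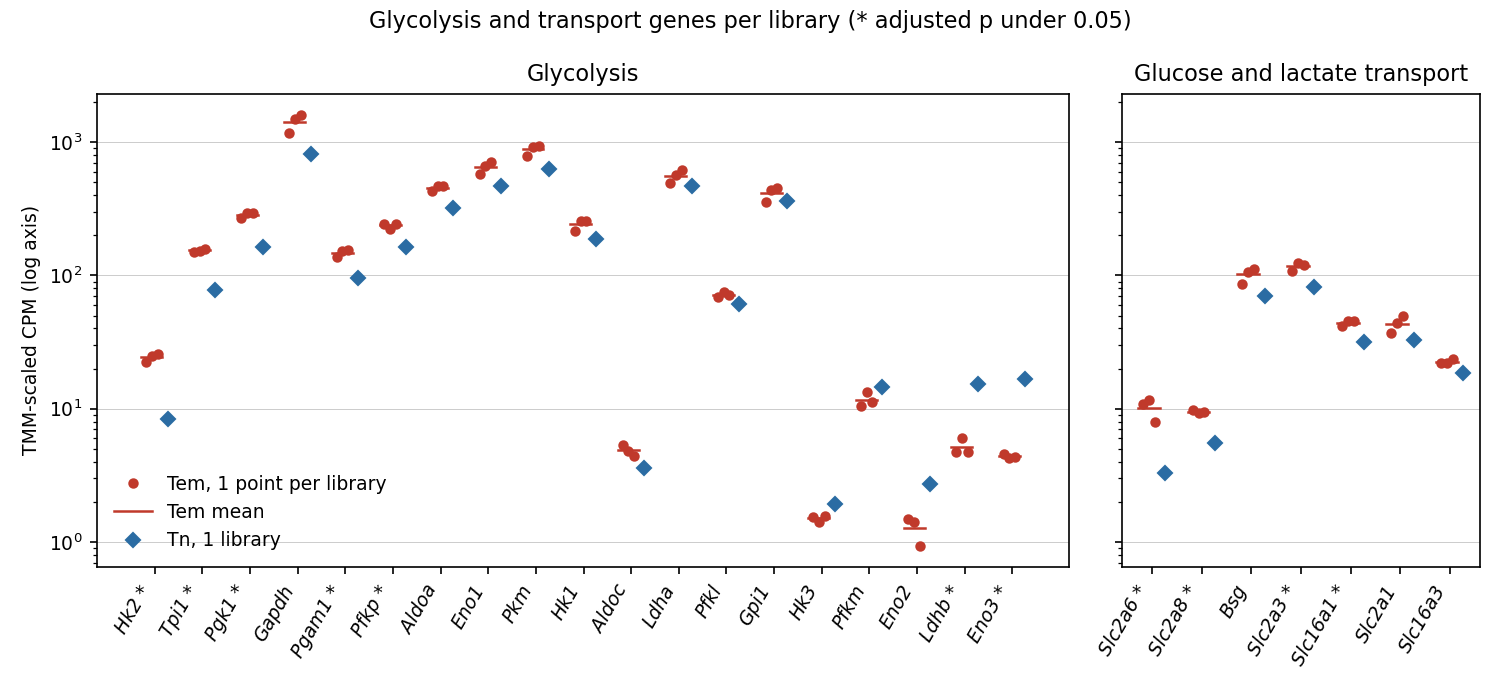
CPM (log axis) of genes of glycolysis and of glucose and lactate transport, with 1 point per library, Tem in red with a line at the Tem mean, and Tn in blue. Hk2 lies at 24.4 in Tem and 8.39 in Tn, and Ldha at 560 and 471.

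Glucose and lactate transporters rose as a list (7 genes, median log2 fold change 0.51, adjusted p = 0.0137; adjusted p = 0.746 with an estimated correlation). With TPM its median was 0.12 (adjusted p = 0.0324). Over all genes 4 rose and 3 did not pass; adjusted over the list alone, 5 rose. Slc2a6, a lysosomal hexose transporter, rose by 1.48 ± 0.26 and Slc2a8 by 0.74 ± 0.17 (adjusted p = 0.0180 and 0.0371). Slc2a3, the neuronal and lymphocyte glucose transporter GLUT3, rose by 0.51 ± 0.12, from 81.9 to 117 ± 7.88 CPM, and Slc16a1, the monocarboxylate transporter MCT1, by 0.46 ± 0.12, from 31.9 to 44.2 ± 2.12 CPM (adjusted p = 0.0421 and 0.0494). Without Tem replicate 2 or 3, Slc2a8, Slc2a3 and Slc16a1 no longer passed (adjusted p from 0.119 to 0.227). Slc2a1, which encodes GLUT1, stood at 43.3 ± 6.29 CPM in Tem and 32.9 in Tn (0.38 ± 0.19, adjusted p = 0.200). Slc16a3, which encodes the lactate exporter MCT4, and its chaperone gene Bsg had log2 fold changes of 0.28 and 0.53 (adjusted p = 0.201 and 0.0937).

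Regulators of glycolysis went both ways: of 15 tested, 4 rose and 4 fell over all genes, and 4 rose and 5 fell adjusted over the list alone (list adjusted p = 0.988). Hif1a, the transcription factor of the hypoxia response, rose by 1.46 ± 0.16, from 259 to 714 ± 57.3 CPM (adjusted p = 0.00607), and Bhlhe40 by 2.74 ± 0.20 (adjusted p = 0.00223). Pdk1 (ENSMUSG00000006494, chromosome 2, 71873224 to 71903858, plus strand), a kinase that inhibits pyruvate dehydrogenase, fell by 2.46 ± 0.16, from 213 to 38.4 ± 4.48 CPM (adjusted p = 0.00196). Myc, a growth transcription factor, and Pfkfb4 fell by 0.76 ± 0.13 and 1.04 ± 0.22 (adjusted p = 0.0173 and 0.0308). Pfkfb3 and Pdha1 had log2 fold changes of 0.00 and −0.01.

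No other metabolic list passed with camera. Oxidative phosphorylation had 0 of 29 genes past the threshold, also adjusted over the list alone (median 0.25, adjusted p = 0.0622). In this limma model 5322 of all genes had an unadjusted p under 0.05. The tricarboxylic acid cycle had 1 rise, Idh3a (0.77 ± 0.17), and 1 fall, Idh2 (−1.78 ± 0.21), among 18 genes (adjusted over the list alone, 0 and 1; median 0.20, adjusted p = 0.139). Without Tem replicate 1 both lists passed (adjusted p = 0.000925 and 0.0112), as did pentose phosphate (adjusted p = 0.0397), and with FPKM the first pair did (both 0.0395), as with no filter. Oxidative phosphorylation also passed with a length trend removed. The pentose phosphate list had 1 rise of 9, Rpe (0.67 ± 0.11), the same adjusted over the list alone (median 0.31, adjusted p = 0.171). Fatty acid oxidation had 0 of 11, also adjusted over the list alone (median 0.28, adjusted p = 0.358). Fatty acid and sterol synthesis had 2 rises, Scd2 (0.70) and Acaca (0.44), and 2 falls among 13, one of them Fasn (−0.56), also adjusted over the list alone. Its median was 0.16 while its mean was −0.06 and its test pointed down (adjusted p = 0.982). Amino acid transport had 1 rise of 10, Slc38a1 (0.46), and 0 adjusted over the list alone (adjusted p = 0.988). One-carbon metabolism had 3 rises of 10, also adjusted over the list alone, among them Tyms (1.08) and Psat1 (0.80), which serve nucleotide and serine synthesis (adjusted p = 0.426). With TPM the medians of oxidative phosphorylation, the tricarboxylic acid cycle, pentose phosphate, both fatty acid lists, amino acid transport (−0.35) and one-carbon metabolism (−0.29) were negative, as were Rpe and Acaca, relative to a median of −0.32 over all genes.

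The effector memory and homing lists were higher in Tem and the naive list was lower, by camera at the preset correlation. Of 20 effector memory genes 19 rose, also adjusted over the list alone (median 2.46, adjusted p = 5.82e-13; adjusted p = 0.746 with an estimated correlation). Itgb1, the beta 1 integrin, rose by 3.47 ± 0.20, from 134 to 1493 ± 190 CPM, Ly6c2 by 3.60 ± 0.20 and Anxa1 by 3.49 ± 0.21. Itgb7, the gut-homing integrin subunit, had a log2 fold change of −0.10 (adjusted p = 0.755). Of 18 naive T cell genes 14 fell and 1 rose; adjusted over the list alone, 16 fell and 1 rose (median −1.43, adjusted p = 1.21e-11; adjusted p = 0.746 with an estimated correlation). Dapl1 fell by 4.43 ± 0.29. Klf2 and S1pr1, which serve exit from lymphoid organs, had log2 fold changes of −0.87 and −0.46 (adjusted p = 0.0582 and 0.107). Of 19 homing and chemokine receptor genes 11 rose and 2 fell, and 11 and 3 adjusted over the list alone (median 1.07, and 0.68 with TPM; adjusted p = 0.0270; adjusted p = 0.820 with an estimated correlation, and 0.106 with a filter on a mean of 5 CPM). Cx3cr1, the fractalkine receptor, rose by 3.24 ± 0.21, and Selplg had a log2 fold change of 0.07. The effector memory, naive and homing lists share genes with the sort gates, Cd44 in the first and Ccr7 in the others.

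Genes of the T helper type 1 (Th1) and follicular helper programmes rose. Of 10 Th1 genes 9 rose, also adjusted over the list alone (median 1.96, adjusted p = 1.04e-05; adjusted p = 0.798 with an estimated correlation). Tbx21, the Th1 master regulator T-bet, rose by 2.34 ± 0.19, from 27.3 to 141 ± 20.8 CPM, and Ifng, interferon gamma, by 2.44 ± 0.24, from 12.5 to 71.0 ± 14.2 CPM (adjusted p = 0.00288 and 0.00438). Tnf had a log2 fold change of −0.28 (adjusted p = 0.271). All 8 follicular helper genes rose, also adjusted over the list alone (median 1.84, adjusted p = 1.77e-06; adjusted p = 0.746 with an estimated correlation), among them Il21 (2.98 ± 0.17) and Pdcd1 (2.62 ± 0.13). The inhibitory receptor list also holds genes that encode no inhibitory receptor: Entpd1, Tox, Nr4a1, Nr4a2 and Nr4a3. It shares Pdcd1 with the follicular helper list. Of its 13 genes 8 rose and 1 fell, and 10 and 1 adjusted over the list alone (median 1.26, adjusted p = 0.000127, and adjusted p = 0.746 with an estimated correlation). Tox, a regulator of exhausted T cells, rose by 1.80 ± 0.13, and Ctla4 had a log2 fold change of 0.05. Of 10 cytotoxicity genes 8 rose, also adjusted over the list alone (median 1.46, adjusted p = 0.000928; adjusted p = 0.798 with an estimated correlation). Gzma, Fasl and Nkg7 rose by 2.64 ± 0.45, 1.92 ± 0.18 and 1.87 ± 0.21, and Prf1, perforin, had a log2 fold change of 0.17 (adjusted p = 0.690). The list of NK and NKT cell markers, described with the other cell types, was higher as well.

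Lists of the other helper types did not pass at the main settings. Th2 had 3 rises of 7, also adjusted over the list alone: Il1rl1 (2.5), Maf (1.59) and Gata3 (1.14) (median 1.07, list adjusted p = 0.0622; 0.820 with an estimated correlation). It passed with TPM (adjusted p = 0.00999), TPM without structural RNA genes (0.0121), quantile normalization (0.0318) and median-of-ratios (0.0498). It also passed with no filter, and without Tem replicate 1 (0.0488) or 3 (0.0150), but not 2 (0.0548). Th17 had 2 of 6, also adjusted over the list alone: Rora (1.79) and Ahr (1.40) (list adjusted p = 0.139). Of 10 regulatory T cell genes, 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.571). Foxp3, the master regulator of regulatory T cells, fell by 1.11 ± 0.23, from 157 to 73.3 ± 14.5 CPM (adjusted p = 0.0285), and Lrrc32 and Itgae fell by 2.66 ± 0.14 and 1.33 ± 0.23, while Nrp1 rose by 2.39 ± 0.12. Costimulation and activation genes had 5 rises and 1 fall among 11, and 5 and 2 adjusted over the list alone (adjusted p = 0.456). Egr2 and Icos rose by 1.44 and 1.09, Egr1 fell by 1.34 ± 0.32, and Cd69 had a log2 fold change of −1.28 (adjusted p = 0.0501).

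The cell cycle lists were higher in Tem, and their genes were also well expressed in Tn. With TPM their medians were 0.81 (G2 and M phase) and 0.63 (S phase). Of 21 G2 and M phase genes 19 rose, and 21 adjusted over the list alone (median 1.24, adjusted p = 3.39e-09; adjusted p = 0.798 with an estimated correlation). Mki67, a marker of cycling cells, rose by 1.24 ± 0.20, from 452 to 1069 ± 120 CPM (adjusted p = 0.0143), and Ccna2, cyclin A2, by 1.41 ± 0.24. Aurkb and Aurka had log2 fold changes of 0.74 and 0.75 (adjusted p = 0.0512 and 0.0852). Of 19 S phase genes 13 rose, and 17 adjusted over the list alone (median 1.02, adjusted p = 3.7e-07; adjusted p = 0.798 with an estimated correlation). Ccne2 and Rrm2, a subunit of ribonucleotide reductase, rose by 1.56 ± 0.21 and 1.29 ± 0.18, and Mcm2 and Mcm4 had log2 fold changes of 0.39 and 0.53.

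The interferon response, stress and dissociation, and ribosomal protein lists were lower in Tem by camera at the preset correlation. Of 18 interferon response genes 12 fell, and 14 adjusted over the list alone (median −1.05, adjusted p = 1.01e-08; adjusted p = 0.746 with an estimated correlation). Oasl1, Oasl2 and Usp18, an interferon-induced deubiquitinating-type protease, fell by 2.23 ± 0.23, 2.20 ± 0.17 and 2.03 ± 0.18, and Gbp3 and Oas1a had log2 fold changes of −0.07 and 0.02. Of 13 stress and dissociation genes 11 fell, also adjusted over the list alone (median −1.34, adjusted p = 1.13e-06; adjusted p = 0.746 with an estimated correlation). Jun stood at 104 ± 47.6 CPM in Tem and 845 in Tn (−3.12 ± 0.49, adjusted p = 0.0139), and Fos at 51.4 ± 34.9 and 404 (adjusted p = 0.0299). Hsp90aa1 and Hsph1, heat shock proteins, had log2 fold changes of 0.05 and −0.32. Of 20 ribosomal protein genes 4 fell, and 13 adjusted over the list alone (median −0.64, adjusted p = 1.84e-06; adjusted p = 0.820 with an estimated correlation), with Rplp1 lowest at −1.00 ± 0.16. With TPM the median of this list was −1.00, beside −0.32 over all genes. Structural RNA took 23.9% of reads in Tn and at most 16.9% in a Tem library. With structural RNA genes left out, the median of the ribosomal protein list stayed at −0.64, and at −0.71 with TPM without them. Apoptosis genes went both ways, with 4 rises and 2 falls among 13, and 4 and 3 adjusted over the list alone (adjusted p = 0.967). Pmaip1, which promotes apoptosis, rose by 1.48 ± 0.15, and the survival gene Bcl2l1 rose 2.15-fold (adjusted p = 0.0103).

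Markers of other cell types mostly stayed at low levels in both groups. The natural killer (NK) and NKT list was higher in Tem, with 5 rises and 1 fall among 6, also adjusted over the list alone (median 1.78, adjusted p = 0.00935; adjusted p = 0.798 with an estimated correlation, and 0.102 with a filter on a mean of 5 CPM). Klrd1, which encodes CD94, rose by 3.49 ± 0.20 and Eomes by 1.28 ± 0.21. The fall was in Cd1d1, whose product both gates exclude. Gamma delta T cell genes had 2 rises of 5, Tcrg-C2 (3.22) and Tcrg-C4 (2.10), and dendritic cell genes 3 of 7, Siglech (3.30), Xcr1 (2.65) and Itgax (2.04). Monocyte and macrophage genes had 3 of 14, Hmox1 (1.63), Itgam (1.15) and Cd68 (1.15). Their lists had adjusted p = 0.0622, 0.121 and 0.197 but passed with TPM (0.000482, 0.0156 and 0.0127), and the dendritic cell list also with no filter. With TPM without structural RNA genes the gamma delta and monocyte lists passed (0.0126 and 0.0360). Gamma delta also passed with median-of-ratios (0.0498), with a length trend removed, and without Tem replicate 3 (0.0328). For these 3 lists the counts adjusted over the list alone were the same but for 1 dendritic cell gene that fell. B cell genes had 1 rise of 7, Cd22 (2.76 ± 0.29, from 10.3 to 74.3 ± 18.5 CPM), and Cd74 had a log2 fold change of −0.62 (list adjusted p = 0.988). Plasma cell genes had 1 of 5, Irf4 (0.86), erythroid genes 1 of 6, Tfrc (0.49), and neutrophil genes 0 of 5, with list adjusted p = 0.245, 0.456 and 0.240 and the same counts adjusted over the list alone. Without Tem replicate 3 the neutrophil list was lower in Tem (median −1.33, adjusted p = 0.00369 at the preset correlation); with all libraries its estimated correlation was 0.971 (adjusted p = 0.858). Tfrc was lower in Tem with TPM (−0.31) and with TPM without structural RNA genes (−0.03). Stromal and endothelial genes had 1 rise, Cdh5 (1.28), and 2 falls, Kdr (−1.18) and Pecam1 (−0.55), among 3, also adjusted over the list alone (adjusted p = 0.426). T cell identity genes had 1 rise of 12, Zap70 (0.60), and 0 adjusted over the list alone (adjusted p = 0.456). The CD8 T cell and platelet lists were too short to test: Cd8a and Cd8b1 had log2 fold changes of 1.19 and −0.12, and Itga2b −1.38, none past the threshold over all genes.

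**Figure D3:**
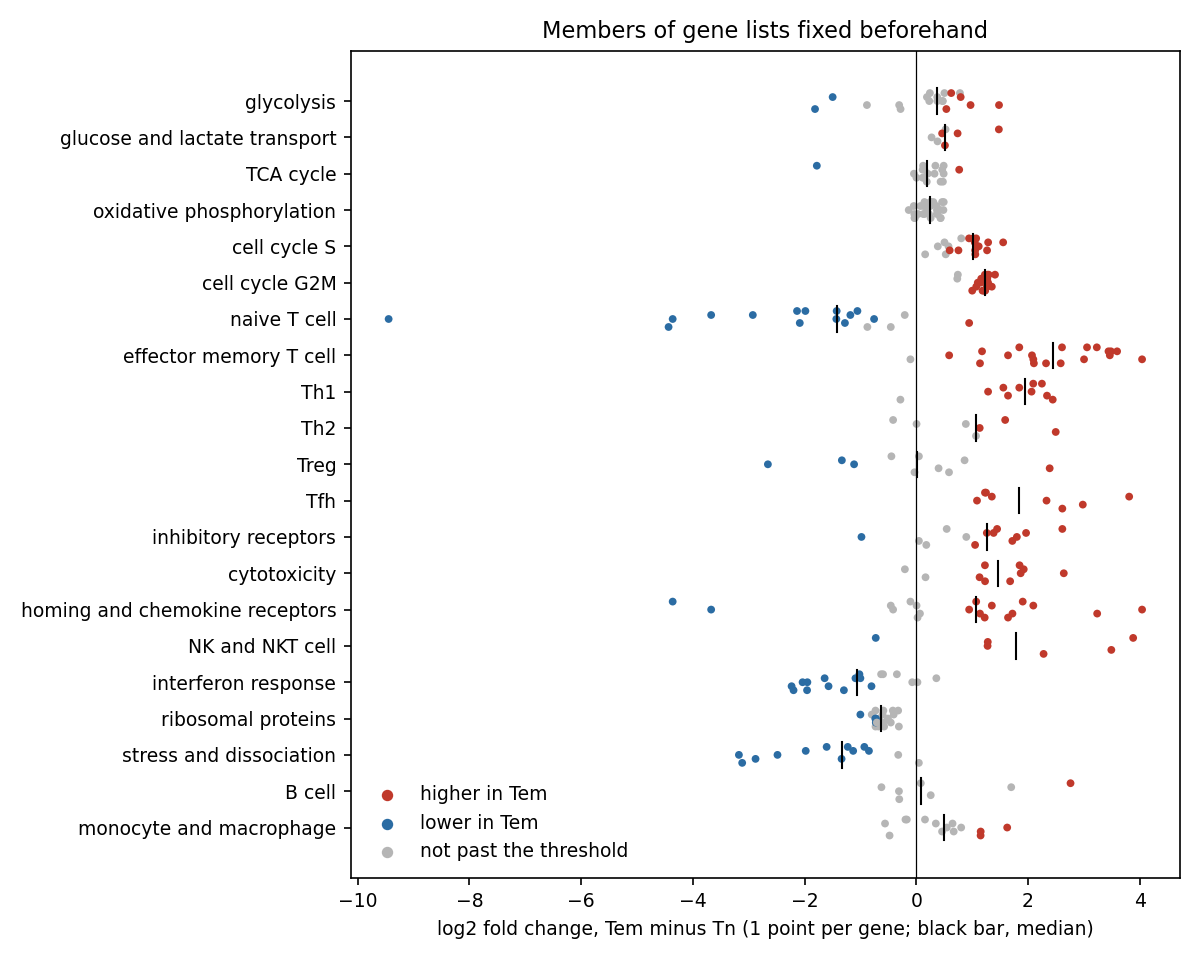
Log2 fold change of Tem over Tn (horizontal axis) for members of 21 of the fixed lists, with 1 point per gene, genes past an adjusted p of 0.05 in red (higher) or blue (lower), and a black bar at the median. Effector memory genes have a median of 2.46, naive genes −1.43, and glycolysis genes 0.38.

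Lists chosen by the study gave 0 calls of 21 with camera (6 at an unadjusted p under 0.05), which is not independent evidence since how they were chosen is not given in the sources used here. Camera called 5 as higher without Tem replicate 1, 1 without replicate 2, 2 without replicate 3, 9 of 23 with no filter, 2 with TPM (the Th1 and Th17 lists, adjusted p = 0.000663 and 0.0295) and 2 with FPKM (the metabolic and complex I lists, both 0.0422). Its glycolysis list (26 genes tested, 18 of its 30 members shared with the list of 19 above) had 5 rises and 5 falls, and 7 and 5 adjusted over the list alone. Its median was 0.24 and its mean −0.07 (adjusted p = 0.831). Its metabolic list had 14 rises and 10 falls among 168 genes, and 10 and 7 adjusted over the list alone (adjusted p = 0.108; 0.00185 without Tem replicate 1, and 0.320 and 0.462 without 2 and 3). Its Th1 list had 10 rises and 3 falls of 20 (adjusted p = 0.108; 0.0354 and 0.00355 without Tem replicates 2 and 3), its Th2 list 8 and 2 of 20, its Th17 list 3 and 0 of 9, and its regulatory T cell list 1 and 3 of 10. The Th17 list passed without Tem replicate 3 (adjusted p = 0.00966). Fry, which asks whether a list's genes move one way on balance, called 2 as lower: monocarboxylate transporters and suppressors of the pyruvate dehydrogenase complex (adjusted p = 0.0403 and 0.0486). The first had 1 rise and 1 fall of 8, with 5 genes above 0 and a median of 0.34 (camera adjusted p = 0.945). Its fall was in Slc16a5, named after its values were seen, which fell by 5.14 ± 0.26. The second had 1 rise and 1 fall of 3, the fall being Pdk1 (median −0.89, camera adjusted p = 0.399). The authors' own results table lists 15502 genes, with 2356 higher and 2800 lower in Tem at an adjusted p under 0.05. Over 14103 genes in both tables, fold changes had Pearson's r of 0.952 and Spearman's rho of 0.986 across genes, which are not independent replicates. All 2946 genes called by both had the same direction. The authors tested 6 genes that had no read in these 4 libraries, and the p-values in their table correspond to 8.29 degrees of freedom. Whether further libraries entered it is not given in the sources used here, and both tables hold these 4, so their agreement is no independent check.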

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

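Chosen after seeing the data were the tests with structural RNA genes left out (also with TPM), with a gene length trend removed, and with edgeR at the deposited scaling. No paired analysis was possible because the groups share 1 replicate number, and a block would leave 0 residual degrees of freedom. Changed genes stayed within 1.5 times the 3072 reported for both pseudocounts, the filter on the mean, median-of-ratios, quantile normalization, both variance priors, edgeR, DESeq2 and the other added settings (2445 to 3858). Genes changed, higher and lower numbered 1191, 474 and 717 with no filter, 230, 37 and 193 with TPM, 1544, 1025 and 519 with FPKM, and 737, 329 and 408 with TPM without structural RNA genes. With no filter 26008 genes were tested and the prior fell to 1.21 degrees of freedom; for TPM and FPKM the cause was not tested. Leaving out each Tem library gave 1456 to 7673 changed, 894 to 4407 higher and 562 to 3266 lower, and leaving 2 Tem libraries rests the spread on 1 difference. The 3072 calls kept their direction wherever tested except with TPM (2919 of 2970), FPKM (2941 of 2942) and TPM without structural RNA genes (3013 of 3017). Named genes that reversed were Rpe (−0.024), Acaca (−0.10) and Tfrc (−0.31) with TPM, and Tfrc (−0.030) with TPM without structural RNA genes; the cause was not tested. Of 197 named genes, 92 lost their call with TPM, 66 with no filter, 60 with TPM without structural RNA genes, 29 with FPKM, 25 and 17 without Tem replicate 2 and 3, and none without Tem replicate 1, where 37 gained one. With no variance trend 20 of the named genes lost their call. With Tem replicate 3 alone against Tn, 50 of them moved from the main value by at least the SD of the Tem libraries, and 0 called genes reversed. Of values past the threshold in neither setting, 142 changed sign. The glycolysis list passed with no filter (0.38, adjusted p = 0.0258), quantile normalization (0.40, adjusted p = 0.0317) and without Tem replicate 1; over its settings adjusted p ran from 0.0258 to 0.858, and leaving out a library gave medians of 0.38 to 0.46. Lists higher and lower in Tem numbered 10 and 4, against 16 higher with no filter, 14 with TPM, and 8 and 4 with the filter on the mean (homing and NK lists lost). Leaving out Tem replicate 1 or 3 also changed these counts. They were 0 and 0 with an estimated correlation (37 lists, camera), and 4 and 2 with fry. Fry called the effector memory, follicular helper, inhibitory receptor and NK lists higher, and the naive and interferon lists lower. It did not call the transport, S phase, G2 and M phase, Th1, cytotoxicity, homing, stress and ribosomal protein lists. The called lists kept the sign of their median under each scaling. Depth limits genes under the floor of 3 reads, 0.0645 to 0.0886 CPM.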

Other observations

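The gene families in the first 2 paragraphs were chosen after seeing the data, as were the tests on the stress genes, on the cell cycle genes of the Tn library and on a gene length trend. Because the same values led to the choice of the families, their adjusted p-values are descriptive and are no evidence of a change. The other tests on Tem replicate 1 were set once it was seen to stand apart and before their results. Interferon-inducible GTPases, which attack vacuoles of intracellular pathogens, fell as a family in Tem: 15 of 18 fell and 0 rose (median −1.30, adjusted p = 6.09e-13; adjusted p = 0.404 with an estimated correlation). Gbp2b fell by 4.15 ± 0.26, from 32.6 to 1.37 ± 0.258 CPM, Igtp by 1.63 ± 0.16, from 639.5 to 207 ± 21.0 CPM, and Iigp1 by 1.26 ± 0.11. The Ifitm family went the other way, with 4 of 4 higher (median 2.86, adjusted p = 0.00072; adjusted p = 0.404 with an estimated correlation), Ifitm3 by 1.91 ± 0.34. Class I and II MHC genes had 6 falls and 0 rises among 27 (median −0.27, adjusted p = 0.000254; adjusted p = 0.404 with an estimated correlation). A set of 20 receptor genes of interleukins, interferons and TGF beta, picked by hand, had 8 falls and 4 rises, a balance that depends on the genes picked (median −0.27, adjusted p = 0.00682; adjusted p = 0.404 with an estimated correlation). Il6ra fell by 3.39 ± 0.21, from 232 to 21.9 ± 3.71 CPM, Il4ra fell by 2.57 ± 0.13, from 282 to 47.2 ± 3.72 CPM, and Il7r by 1.28 ± 0.21, while Il2rb rose by 1.03 ± 0.19. Suppressors of cytokine signalling did not pass as a family (8 genes, 2 falls, adjusted p = 0.310), though Socs3 fell by 2.69 ± 0.16, from 322 to 49.6 ± 5.71 CPM.

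Killer cell lectin-like receptors had 9 rises and 0 falls among 11 (median 2.28, adjusted p = 1.02e-06; adjusted p = 0.404 with an estimated correlation). Replication histones, made in S phase, had 44 rises and 0 falls among 63 (median 1.07, adjusted p = 7.98e-16; adjusted p = 0.404 with an estimated correlation). Integrin subunits had 12 rises and 4 falls among 22 (median 0.83, and 0.22 with TPM; adjusted p = 0.0310; adjusted p = 0.404 with an estimated correlation). Itga4 rose by 1.72 ± 0.21, from 528 to 1747 ± 140 CPM, and Itga6 fell by 1.40 ± 0.12. Annexins had 6 rises of 8 and S100 genes 5 of 8 with 0 falls in either (median 0.92 and 1.22, adjusted p = 0.000222 and 0.00597; adjusted p = 0.404 with an estimated correlation for both). Medians of these families, the GTPases, the Ifitm and the MHC genes kept their sign under TPM, FPKM, median-of-ratios and quantile scaling, but most calls of single members were lost with TPM. With TPM there were 3 lectin-like receptors, 0 histones, 0 integrins, 1 annexin, 0 S100 and 1 Ifitm gene called higher, and 3 GTPases and 1 MHC gene lower. With FPKM these were 5, 12, 5 (and 1 integrin lower), 4, 4 and 3 higher, and 14 and 3 lower. The cytokine receptors had 3 falls and 0 rises with TPM, and 5 and 4 with FPKM. Medians also moved for histones (0.69) and annexins (0.50) with TPM, and for MHC genes (−0.57 and −0.11) and cytokine receptors (−0.60 and −0.16) with TPM and FPKM. Close paralogs share reads, so values of single GTPase, lectin-like receptor, histone, MHC and Ly6c genes depend on how reads were assigned. Ly6c1 fell by 7.02 while Ly6c2 rose by 3.60. Cd22 rose while the B cell genes Cd79a and Ms4a1 stayed under 1 CPM in all 4 libraries.

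Tem replicate 1 stood apart: over 8539 genes with a mean of at least 10 CPM its distance from the other Tem libraries was 2.97 times their distance from each other (95% bootstrap interval over genes 2.87 to 3.07), against 0.610 and 0.705 for replicates 2 and 3. The ratio stayed at 2.54 (2.46 to 2.62) with a gene length trend removed, at 2.63 (2.55 to 2.72) with libraries thinned to the shallowest, and at 2.33 (2.24 to 2.42) on protein-coding genes alone, which argues against each as the whole cause. Several non-coding classes were higher in it than in the other Tem libraries, but the ratio on protein-coding genes shows that its distance was not confined to them. Median log2 differences were 1.19 for 740 genes of the annotation class TEC, 1.16 for 80 sense intronic genes, and 0.64 for antisense genes. They were 0.43 for lincRNA and processed transcripts, 0.14 for processed pseudogenes and −0.11 for protein-coding genes. More unspliced RNA may be part of the excess in non-coding classes, which was not tested. The mice behind each pool stay open since the labels do not give them.

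The stress and dissociation list was lower in Tem, and the single Tn library was handled once, so its handling cannot be told apart from its cell type. B cells, monocytes or neutrophils in Tn, which the CD4+ gate would remove at a stated purity of 95%, are argued against as the whole cause. Such cells would bring their abundant transcripts, yet even the markers above the Tem mean exceeded it in Tn by only 60.2, 52.9 and 14.1 CPM in sum. That is 1.76% (up to 8.09% by the spread of the Tem libraries), 1.55% (6.89%) and 0.414% (5.86%) of the excess of 3416 CPM in the 13 stress genes. Jun alone stood at 845 CPM in Tn, against 155 for Cd74, 157 for Ctss and 10.3 for Ngp, the highest marker of each type. Handling shared by libraries numbered 3 was not decided, since Tem replicate 3 minus the other Tem libraries had a median of −0.00132 over 13 genes (−0.83 to 0.21). The Tem libraries also differed among themselves, with Fos at 38.1, 91.0 and 24.9 CPM against 404 in Tn. A difference in activation between naive and effector memory cells may account for it too, and was not tested.

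The Tn library held G2 and M phase transcripts at a median of 41.6% of the Tem level (21 genes, 36.8% to 59.1%). Carry-over of average Tem cells would bring effector memory transcripts at that share or above, but these stood at a median of 18.0% (20 genes), and 16 of them lay below the lowest G2 and M phase gene (permutation test, one-sided p = 6e-05, 100000 permutations of genes, which are not independent). Erythroid precursors, which red cell lysis would not remove but the CD4+ gate would, would lower the erythroid markers in the comparison. The median log2 fold change of these markers was 0.38 (4 markers, −0.11 to 0.49), with Hbb-bs at 3.12 CPM in Tem and 1.98 in Tn. Their list holds Tfrc, which rose here but was lower in Tem with TPM. With so few genes, these values argue only weakly against such cells. Regulatory T cells in the gate were not decided, since their list had a median of 0.0087 (10 genes, −1.11 to 0.63) and Foxp3 was higher in Tn. Cycling of the cells in the naive gate may account for it as a hypothesis, which was not tested, and Tn has 1 library.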
